A study of Homo sapiens with 4 samples.

How the data were processed

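Gene expression was measured in 4 RNA samples of U87, an established human glioma cell line, in which QK (QKI, an RNA-binding protein) had been knocked down. Per the labels, 2 samples came from cells that had also received miR-20a, a microRNA of the miR-17 family, by transduction, and 2 from cells given miR-NT, a control microRNA with a scrambled sequence. Per the labels' protocols, total RNA was extracted with a commercial kit and biotin-labelled cRNA was made from 6 µg of total RNA by the Affymetrix protocol. Each sample was read on 1 single-colour array. The deposited values are log2 probe-set levels, 1 per probe set and array, on a scale the authors did not centre per gene. The submitters' processing notes name the R package affy, without a version. The methods of background correction, normalization and summarization are not given in the sources used here. The log base was taken from the values: the highest, 15.07, lies above what a natural logarithm and below what a log2 of a scanner's maximum would give. The table held 41930 probe sets, 10 of them array controls. The values carry no detection calls, so a level cannot be separated from background here, and the number of arrays limits the precision. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No 2 columns were copies: the arrays of a pair shared at most 128 exactly equal values.

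Probe sets were named through GEO's platform annotation, with symbols checked by Entrez identifier against the RefSeq genes of GRCh38.p14, and 0 symbols had to be changed. Of the probe sets, 37465 named a single gene, 1727 named several and 2728 named none. The array's annotation names no genome build, so no coordinates are given. Each gene was represented by the probe set with the highest mean over all 4 arrays, which gave 18304 genes. Other probe sets of a gene could differ in size or sign, and they are mentioned for some genes only. No filter on low values was applied, and the deposited normalization was kept.

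The comparison of miR-20a with miR-NT was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept and group, all 4 arrays). Two-sided p-values were adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. Values are given as log2 change with its standard error (SE) from this fit, or as group mean ± SD. With 2 arrays against 2, an exact permutation test of a single value cannot go below a p of 0.333, so limma's shared estimate of the spread carries the tests. Its prior had 4.73 degrees of freedom and an SD of 0.098. There were 19 gene lists, tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. The camera test was repeated with an estimated correlation. In that form it rests on the few residual degrees of freedom of 4 arrays. It can then hardly pass any list (smallest camera adjusted p 0.699), so a call lost there decides little. Fry was also run, which tests whether a list's own genes move one way and does not compare them with other genes. The lists were published miR-20a targets, TGF-beta receptors, ligands and SMADs, TGF-beta response genes, E2F and G1/S genes, G2/M and mitosis genes, p53 targets, cholesterol synthesis, hypoxia and glycolysis, type I interferon response, NF-kB and inflammatory genes, ATF4 and unfolded protein response, immediate early genes, YAP and TEAD targets, mesenchymal and matrix genes, glial and neural stem cell genes, microRNA machinery, and markers of epithelial, blood and endothelial cells. They were compiled from general knowledge, as was the published target list.

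The samples, the tests, the lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule named 9 genes whatever their value, among them QKI, MIR17HG, TGFBR2, TGFBR1, SMAD4, CDKN1A, E2F1 and BCL2L11, and 1 further gene that is not reported here. It further named the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p. XIST and Y-linked genes were not named. These other settings were a replicate block, quantile normalization, median centring, removal of genes below the 40th percentile of mean level, eBayes with a trend and robust fit, other ways of joining probe sets, other thresholds, and leaving out each array. Cyclic loess normalization, quantile normalization with an estimated correlation for the lists, a crossed pairing, and removal of trends with gene length and with the number of protein-coding genes whose starts lie within 1000 kb were added after seeing the data, as were 3 further gene lists. The fits were tested on simulated data, over 20 simulations with 200 changed genes each and the spread of these arrays. There, 16.6% of changes of 0.5 log2 units, 94.9% of 1 unit and 99.3% of 1.5 units were recovered, and 5.69% of all calls were false. The simulated genes varied independently, without shifts shared across an array, so these rates may not hold for the calls reported here. The planned test of genes with miR-20a seed sites in their 3′ UTR was not run, since 3′ UTR sequences were not used here.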

Results

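The data comprised 4 arrays of QK-knockdown U87 glioma cells, 2 of cells that had received miR-20a and 2 of cells that had received the non-targeting microRNA miR-NT. The design asked which transcripts differ when miR-20a is supplied to cells depleted of QK. No array of cells without the knockdown was analysed here. The median log2 probe-set level was 7.009 and 6.999 on the miR-NT arrays and 6.969 and 6.972 on the miR-20a arrays. The arrays correlated at r = 0.9961 within miR-NT, 0.9946 within miR-20a and between 0.9908 and 0.9935 across groups. The levels on the miR-20a arrays were spread more widely over probe sets, with SDs of 1.906 and 1.892 against 1.847 and 1.852.

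Among genes past the threshold whose groups did not overlap, the 10 largest increases in miR-20a cells lay between 2.24-fold and 4.05-fold. THBS1, which encodes the matrix glycoprotein thrombospondin-1, rose 3.13-fold, from 9.39 ± 0.03 to 11.03 ± 0.03 log2 units (SD, n = 2 each, limma adjusted p = 0.0062). CEMIP, a hyaluronan-binding protein involved in hyaluronan breakdown, rose 2.83-fold, STC2, a secreted glycoprotein hormone, 2.61-fold, and LRRC15, a membrane protein of mesenchymal cells, 2.28-fold. The other probe set of CEMIP changed by only 0.12 log2 units and that of LRRC15 by 0.29. BAMBI, a decoy receptor of the TGF-beta family, rose 2.25-fold, and ID2, an inhibitor of basic helix-loop-helix transcription factors, rose 2.24-fold. CYTIP, a cytohesin-interacting protein, showed the largest fold, 4.05, from 6.77 ± 0.41 to 8.79 ± 0.23 log2 units (limma adjusted p = 0.020), and its arrays were the most spread of the 10. ERMN, a cytoskeletal protein known from oligodendrocytes, rose 2.95-fold, LBH, a transcriptional cofactor, 2.47-fold, and CALCB, a calcitonin gene-related peptide, 2.36-fold from a low level of 5.24 ± 0.02.

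Among genes past the threshold whose groups did not overlap, the 10 largest decreases were smaller, between 1.55-fold and 2.27-fold. Some genes that did not pass had larger negative changes than the last of these. CHI3L1, the secreted glycoprotein YKL-40 used as a marker of mesenchymal glioma, was 2.18-fold lower in miR-20a cells, at 12.38 ± 0.09 against 13.50 ± 0.02 log2 units (SD, n = 2 each, limma adjusted p = 0.011). LBP, the lipopolysaccharide-binding protein, was 2.06-fold lower and SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was 1.75-fold lower. TMEFF2, a transmembrane protein with follistatin-like domains, was 2.27-fold lower by the probe set used, and 2 of its 3 probe sets had that sign. LAMA5, a laminin chain, was 1.66-fold lower, OLFML2A 1.72-fold, the transporter SLCO4A1 1.71-fold, the nuclear pore protein NUP210 1.70-fold, SIGLEC15 1.58-fold and TXNIP, an inhibitor of thioredoxin, 1.55-fold. The weakest probe set was at -0.16 log2 units for SLCO4A1, -0.04 for NUP210 and -0.18 for CHI3L1. Adjusted p-values of these 10 decreases lay between 0.011 and 0.045 (limma).

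**Figure D1:**
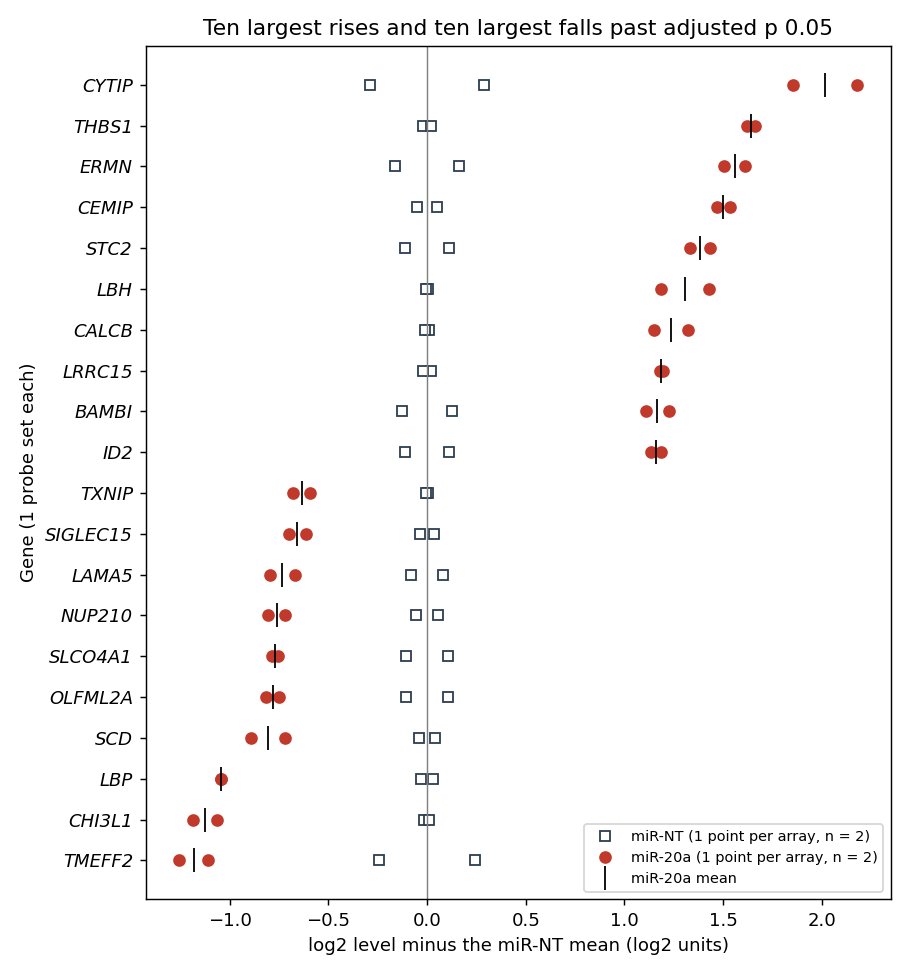
Log2 level of each array minus the miR-NT mean of the same gene (horizontal axis, log2 units) for the 10 largest rises and 10 largest falls past the threshold; squares are the miR-NT arrays, circles the miR-20a arrays (n = 2 each) and vertical ticks the miR-20a means. The genes were chosen among those whose groups do not overlap, and their changes run from 2.02 (CYTIP) to -1.18 (TMEFF2).

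In all, 78 of 18304 genes passed the threshold, 67 higher and 11 lower in miR-20a cells. At an unadjusted p under 0.05 there were 3997 of the 18304 genes (limma). Counts of list members at that threshold, given below, are to be read against this share. The number depended on the settings: 1239 genes passed when the lower 40% of genes by level were left out and 1212 with a mean-variance trend and robust fit, of which 73 and 78 were among the 78, while quantile normalization gave 73 higher and 38 lower. No gene passed without miR-NT replicate 1 or without miR-NT replicate 2 (limma, 1916 and 2841 genes at an unadjusted p under 0.05), while 42 passed without miR-20a replicate 1 and 203 without miR-20a replicate 2.

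QKI, the gene knocked down in all 4 samples, was at 9.28 ± 0.14 log2 units in miR-NT cells and 9.45 ± 0.11 in miR-20a cells (SD, n = 2 each), a difference of 0.18 that did not pass the test (limma adjusted p = 0.38), and only 4 of its 10 probe sets had this sign. MIR17HG, the host transcript of the cluster that encodes miR-20a, was measured near the bottom of the scale, at 3.97 ± 0.01 and 4.20 ± 0.03 (adjusted p = 0.19, limma). Whether its probe set can also detect the transduced sequence was not tested, and the level of miR-20a itself was not measured here.

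Published miR-20a targets went both ways. Of 34 measured members, 1 rose and 1 fell past the threshold over all genes. Adjusted over the list alone, 2 were higher and 1 lower. The thioredoxin inhibitor TXNIP fell by 0.64 ± 0.09 on the log2 scale (SE). MYLIP, a ubiquitin ligase that degrades the LDL receptor, rose by 0.67 ± 0.08. The TGF-beta receptor gene TGFBR2 had a change of -0.27 ± 0.09 (SE, limma adjusted p = 0.15), with both of its probe sets lower. The cell cycle transcription factor E2F1 had a change of -0.27 ± 0.08 (adjusted p = 0.14, limma), again with both probe sets lower. SMAD4, the shared SMAD partner, had a change of -0.20 ± 0.13, with 2 of 5 probe sets of that sign. It rested on miR-20a replicate 2, at 7.70 log2 units against 8.09 on each other array. MICA, a ligand of the NKG2D receptor, had a change of 0.48 ± 0.11 (limma adjusted p = 0.096). CDKN1A, the cell cycle inhibitor p21, had a change of 0.10 ± 0.08, which turned to -0.05 after quantile normalization. BCL2L11, the pro-apoptotic protein BIM, had a change of -0.02 ± 0.09. The list had a median log2 change of -0.06, and camera gave an adjusted p of 0.63, in the direction down, which turned up without miR-20a replicate 2.

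TGF-beta response genes were higher as a list at the preset correlation (camera adjusted p = 0.0020). The call held with a larger p after quantile normalization (camera adjusted p = 0.0199), after cyclic loess (0.0395, added after seeing the data) and with low genes left out (0.0455). With an estimated correlation, a setting in which no list passed, the call was lost (camera adjusted p = 0.70), and fry gave an adjusted p of 0.096. Of 29 measured members, 19 had a higher and 10 a lower mean in miR-20a cells. Past the threshold over all genes, 4 rose and 0 fell, with 12 higher and 3 lower at an unadjusted p under 0.05 (limma). Adjusted over the list alone, 11 rose and 2 fell. The members that rose were THBS1, SNAI2, a transcription factor of epithelial-mesenchymal transition, SMAD7, an inhibitory SMAD, and COL1A1, a chain of type I collagen. SNAI2 rose by 0.93 ± 0.09 and SMAD7 by 0.93 ± 0.11 on the log2 scale (SE). COL1A1 rose by 0.76 ± 0.10 by the probe set used, but only 3 of its 5 probe sets had that sign, and its adjusted p was 0.058 after quantile normalization (limma). The list had a median change of 0.16.

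Among the 23 measured TGF-beta receptors, ligands and SMADs, 3 feedback inhibitors rose and 0 members fell, with 6 higher and 2 lower at an unadjusted p under 0.05 (limma). Adjusted over the list alone, 5 rose and 0 fell. These 3 were BAMBI, SMAD7, which is also a member of the response list, and SMAD6, another inhibitory SMAD. BAMBI rose by 1.17 ± 0.11 and SMAD6 by 0.64 ± 0.08 (SE), the latter with 2 of 4 probe sets of that sign. The type I receptor gene TGFBR1 had a change of 0.34 ± 0.09 (limma adjusted p = 0.11, 1 of 3 probe sets of that sign) and the BMP and activin receptor gene ACVR1 a change of 0.51 ± 0.11 (adjusted p = 0.092, limma). The median of the list was 0.01, and camera gave an adjusted p of 0.41.

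The p53 target list was also higher at the preset correlation (camera adjusted p = 0.0031). The call was lost after quantile normalization (camera adjusted p = 0.0504), after cyclic loess (0.0669, added after seeing the data) and with low genes left out (0.0685). It was also lost with an estimated correlation (camera adjusted p = 0.70), a setting in which no list passed. The correlation estimated for this list, -0.06, was below the preset 0.01, so that loss does not show correlation among its genes. Of 17 measured members, 13 were above and 4 below their miR-NT mean. Over all genes 1 member rose and 0 fell, and 6 were higher and 0 lower at an unadjusted p under 0.05 (limma). Adjusted over the list alone, 6 rose and 0 fell. CCNG1, cyclin G1, rose by 0.73 ± 0.10 on the log2 scale (SE). TP53I3, a quinone oxidoreductase, had a change of 0.57 ± 0.09, RRM2B, a p53-induced ribonucleotide reductase subunit, of 0.51 ± 0.10, and the death receptor gene FAS of 0.38 ± 0.09. CDKN1A, also a member of this list, had a change of only 0.10 ± 0.08 (limma adjusted p = 0.51). The median of the list was 0.16.

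Under the deposited scaling no member of the cell cycle lists passed the test. None of 24 E2F and G1/S genes and none of 25 G2/M and mitosis genes passed over all genes or adjusted over the list alone (limma). At an unadjusted p under 0.05, 1 of the first list was lower and 0 were higher, and of the second 4 were lower and 1 higher. The replication-licensing genes CDC6 and CDT1 had changes of -0.23 and -0.18, and RRM1, a ribonucleotide reductase subunit, 0.20. The change of CDC6 came mostly from miR-20a replicate 2, at 7.33 log2 units against 7.70 on replicate 1 and 7.76 and 7.74 on the miR-NT arrays. Among mitotic genes UBE2C, TPX2, PLK1 and CDC20 had changes of -0.32, -0.28, -0.24 and -0.23. Camera gave adjusted p-values of 0.63 and 0.43. After quantile normalization both lists were lower than other genes (camera adjusted p = 0.030 for each). Both calls were lost with an estimated correlation after quantile normalization (camera adjusted p = 0.65 for each), a setting in which no list passed. Under the deposited scaling fry gave 0.72 and 0.53.

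Among metabolic and stress lists, HK2, the hexokinase that starts glycolysis, rose by 0.73 ± 0.08 on the log2 scale (SE) and was the only member of the 19 measured hypoxia and glycolysis genes past the threshold, also when adjusted over the list alone. The other probe set of HK2 changed by only 0.09. ADM, adrenomedullin, had a change of 0.34, the glycolytic enzyme gene PGK1 0.31 and VEGFA, the angiogenic growth factor, -0.26, and camera gave an adjusted p of 0.42 for the list. Of 15 cholesterol synthesis genes 0 passed over all genes, with 4 higher and 2 lower at an unadjusted p under 0.05 (limma), and adjusted over the list alone 3 rose and 1 fell. The enzymes SC5D, MSMO1 and SQLE had changes of 0.43, 0.34 and 0.33, and SREBF2, their transcription factor, -0.37, with a camera adjusted p of 0.24. The sign was shared by 1 of 2 probe sets of SC5D, 2 of 4 of SQLE and all 3 of SREBF2. Of 21 ATF4 and unfolded protein response genes 0 passed over all genes, with 7 higher and 0 lower at an unadjusted p under 0.05 (limma), and adjusted over the list alone those 7 rose. The chaperone-related genes DNAJB9, HERPUD1 and HSPA5 had changes of 0.60, 0.54 and 0.36 and the mitochondrial folate enzyme gene MTHFD2 0.41. Of these, DNAJB9 had 2 of 3 and MTHFD2 1 of 2 probe sets of that sign. Camera gave this list an adjusted p of 0.074 and fry one of 0.0044.

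Matrix genes went both ways. Of 26 mesenchymal and matrix genes, LOX, the collagen cross-linking enzyme, rose by 0.82 ± 0.09 on the log2 scale (SE) and CHI3L1 fell by 1.12 ± 0.09, while ITGB1, the beta-1 integrin, had a change of 0.50 and COL6A2, a collagen VI chain, of -0.57. Adjusted over the list alone, 5 rose and 2 fell, and camera gave an adjusted p of 0.50. Of 14 YAP and TEAD targets 0 passed over all genes (limma, 4 higher and 1 lower at an unadjusted p under 0.05), and adjusted over the list alone 4 rose and 1 fell. CRIM1, a BMP-binding membrane protein, had a change of 0.69 (adjusted p = 0.053, limma), F3, tissue factor, 0.42, CCN1 0.31 and AMOTL2 -0.33. The median of this list was -0.01 while its mean, 0.08, and camera pointed up (adjusted p = 0.46 by camera).

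No member of the remaining lists passed over all genes (limma). Among 24 type I interferon response genes 3 were higher and 5 lower at an unadjusted p under 0.05, and adjusted over the list alone 1 rose and 3 fell. IFI44L, IFITM1 and OASL had changes of -0.68, -0.46 and -0.35, and IFI6 0.44. Among 18 NF-kB and inflammatory genes 3 were higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 2 rose and 1 fell. The chemokine genes CCL2 and CXCL8 had changes of 0.62 and 0.60, CXCL3 -0.41 and the inhibitor NFKBIA 0.22. Among 20 immediate early genes 3 were higher and 4 lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with MYC at -0.34, DUSP5 at -0.38, ATF3 at 0.33 and IER3 at 0.30. Of 14 microRNA machinery genes 2 were higher and 1 lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with AGO4 at -0.33, DROSHA at 0.26, DDX17 at 0.24 and TNRC6B at -0.19. Camera adjusted p-values were 0.43, 0.63, 0.42 and 0.90 for these lists in turn.

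No marker of glial identity or of another cell type in the fixed lists passed the test. Higher means in miR-20a cells were seen in 7 of 18 glial and neural stem cell genes, 3 of 11 epithelial, 2 of 9 blood and 1 of 10 endothelial markers. Of 18 glial and neural stem cell genes 2 were lower and 0 higher at an unadjusted p under 0.05 (limma), with SOX9 at -0.44, FABP7 at -0.26, NES, which encodes nestin, at -0.21 and SLC1A3 at -0.20. Median log2 changes were -0.10 for the glial list, -0.03 for 11 epithelial, -0.11 for 9 blood and -0.10 for 10 endothelial markers, and 0 members of any of them passed adjusted over the list alone. Camera adjusted p-values were 0.24, 0.43, 0.24 and 0.24, and fry gave 0.019 for the endothelial markers, in the direction down. KRT5, CD3E and ERG, named from the epithelial, blood and endothelial lists, had changes of -0.22, -0.28 and -0.34 at levels between 5.85 and 7.99 log2 units. Across genes, which are not independent replicates, the log2 change rose with the mean level (Spearman rho = 0.29).

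**Figure D2:**
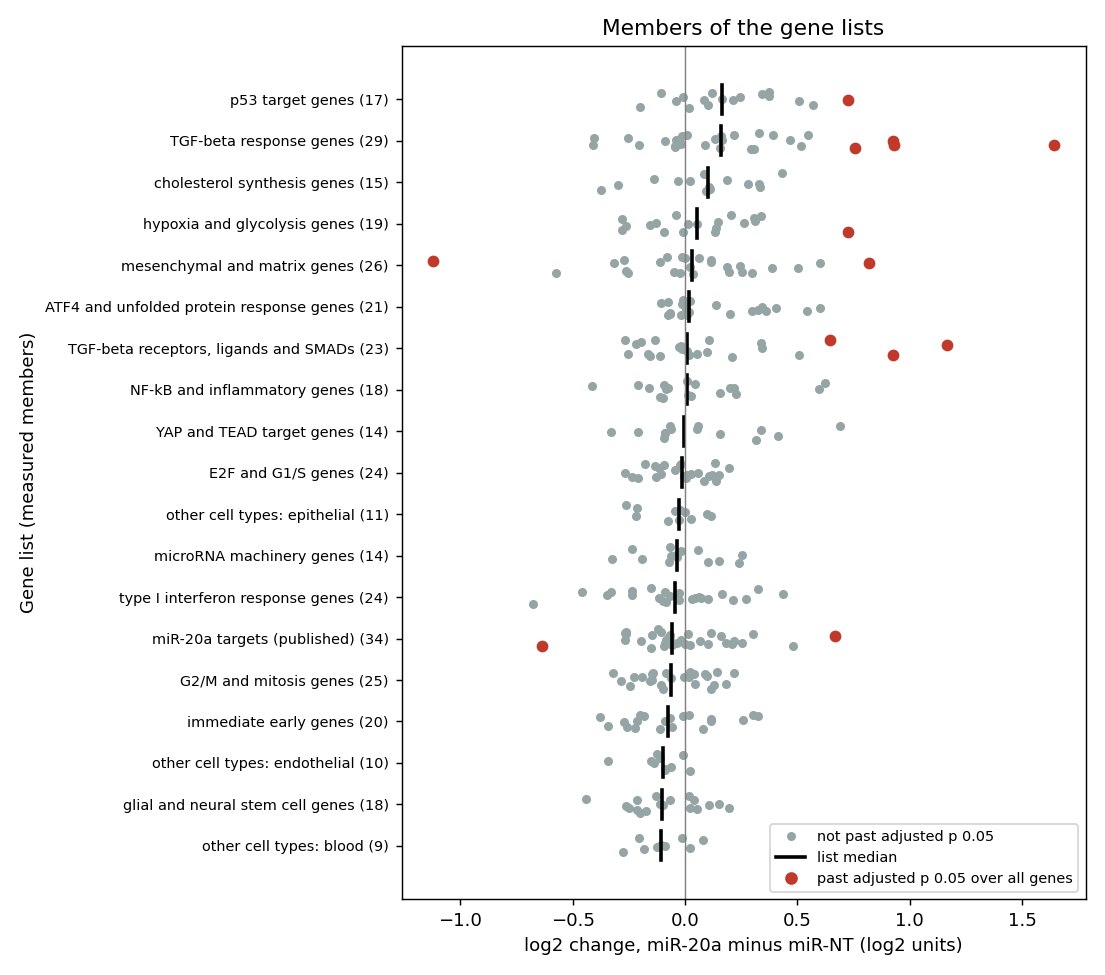
Log2 change of each measured member (points, miR-20a minus miR-NT, horizontal axis in log2 units) in the 19 gene lists (vertical axis, with the number of measured members), with list medians as vertical bars. Points past the threshold over all genes are red: 4 of 29 TGF-beta response genes and 3 of 23 TGF-beta receptors, ligands and SMADs lie to the right, and the published miR-20a targets hold 1 on each side.

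Signs of RNA quality also differed between the groups, and so moved with each of the gene groups above. The 3′ minus 5′ difference of the ACTB control probe sets was 0.27 ± 0.11 log2 units on the miR-NT arrays and 0.49 ± 0.04 on the miR-20a arrays (SD, n = 2 each). The corresponding difference for GAPDH was 0.22 and 0.28. Both controls were higher on both miR-20a arrays than on both miR-NT arrays, and an exact permutation test of such a difference cannot give a p below 0.333.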

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

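The tests in this part were chosen after the results were seen, except the quantile normalization, which was planned. The ACTB control probe sets, which enter no comparison, had a 3′ minus 5′ difference of 0.486 log2 units in miR-20a cells, above the 0.272 of miR-NT cells. Outside the named genes, 2 of 2728 probe sets that name no gene passed the threshold in the fit over all probe sets, with log2 changes of 1.08 ± 0.09 (SE, limma adjusted p = 0.025) and 0.84 ± 0.09 (adjusted p = 0.043, limma). Of 1727 probe sets that name several genes, 0 passed in the same limma fit.

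Rises outnumbered falls among the 78 changed genes, 67 to 11, or 85.9%. Changes were lower for genes with many neighbours, but weakly (rho = -0.17 across genes). The groups are not alone in this: rho was -0.13 between the miR-20a replicates and 0.08 between the miR-NT replicates (1 minus 2 in each). With the trends with gene length and neighbourhood removed, 83.7% of the calls were still rises (95% exact binomial interval 74.5 to 90.6%, treating genes as independent). Removing trends this weak left 77 of the 78 genes called and could hardly have moved the share. The values thus argue only against these fitted trends as the whole cause. The wider spread of levels on the miR-20a arrays stays open: quantile normalization lowered the share to 65.8% (interval 56.2 to 74.5%), but through more falls (38 against 11), while rises numbered 73 against 67, and 69 of the 78 genes were shared. RNA integrity also stays open and cannot be told apart from the treatment, because the ACTB difference was 0.214 higher in miR-20a cells and each group lies wholly on its own side. Of the 3 ways to split the arrays 2 and 2, only the real one, 1 split, gave calls (78, against 0 for both others), which is too few splits for a share under 0.05, and an effect of miR-20a itself was not tested separately.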

How the results depend on the processing

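The 35 named genes that passed kept their direction under quantile normalization, median centring, cyclic loess, trend removal and the mean of all probe sets. As their groups do not overlap, no left-out array could turn them. They were chosen for large changes, which the other settings leave as they are. All 35 lost their call with the replicate block, with the crossed pairing and without either miR-NT array. The count of 78 changed genes moved to 1239 with low genes left out, 1212 with a trend and robust fit, 153 with the mean of all probe sets per gene, 136 with median centring, 39 when every probe set was tested and 2 at an adjusted p under 0.01. It was 111 with quantile normalization (65.8% rises), and, added after seeing the data, 89 with cyclic loess (69.7% rises) and 92 with the length and neighbour trends removed. Leaving out 1 array gave 0 to 203 genes: 0 without either miR-NT array, 42 without miR-20a replicate 1 and 203 without miR-20a replicate 2, where the lone sample is assumed to vary like the other group. With the replicate number as a block 0 genes passed (limma, 3272 at an unadjusted p under 0.05), with 1 residual degree of freedom fewer. The numbers do not pair the samples: the replicate differences of the 2 groups correlated at r = -0.107 across genes. The crossed pairing, added after seeing the data, also gave 0 genes (limma, 3843 at an unadjusted p under 0.05). The count of called lists, 2, was 1 with low genes left out, 0 with an estimated correlation, 0 with quantile normalization and an estimated correlation together (added after seeing the data), 2 with the replicate block and 2 to 3 over the left-out arrays. It was 3 with quantile normalization, with cyclic loess and by fry, of which 1 each was among the 2. With quantile normalization and cyclic loess 2 of the 3 were the cell cycle lists, lower with adjusted p-values of 0.0303 each and of 0.0405 (E2F and G1/S) and 0.0395 (G2/M), and by fry they were p53 targets (0.0194), ATF4 genes (0.0044) and endothelial markers (0.0195, lower). Without miR-NT replicate 1 the ATF4 list also passed (0.0493). TGF-beta response genes had adjusted p-values of 0.699 with an estimated correlation, 0.652 with quantile normalization and an estimated correlation and 0.0955 by fry, and passed in the other alternatives. The p53 targets had 0.0504 with quantile normalization, 0.0685 with low genes left out, 0.0669 with cyclic loess, 0.699 with an estimated correlation and 0.652 with that and quantile normalization. The direction of published miR-20a targets turned up without miR-20a replicate 2 (adjusted p-values 0.477 to 0.927 over the left-out arrays). None of the other turns of direction was a called result: TGF-beta receptors, ligands and SMADs turned down with the mean of all probe sets (0.94), cholesterol synthesis with quantile normalization (0.745, 0.826 with an estimated correlation) and cyclic loess (0.811), hypoxia and glycolysis with cyclic loess (0.811), and mesenchymal and matrix genes with quantile normalization (0.745, 0.863 with an estimated correlation) and cyclic loess (0.576). MicroRNA machinery turned up with low genes left out (0.819). Single genes that turned were QKI (-0.080) and SMAD4 (0.0034) with the mean of all probe sets, CDKN1A with quantile normalization (-0.048) and cyclic loess (-0.036), and BCL2L11 with median centring (0.015) and the mean of all probe sets (0.025). Over the left-out arrays the adjusted p was 0.352 to 0.924 for E2F and G1/S genes and 0.086 to 0.854 for G2/M genes, both turned up without miR-20a replicate 2, 0.262 to 0.95 for NF-kB genes, turned down without miR-NT replicate 2, 0.249 to 0.966 for mesenchymal and matrix genes, turned down without miR-20a replicate 1, and 0.477 to 0.949 for microRNA machinery, turned up without miR-NT replicate 1 or miR-20a replicate 2. Likewise BCL2L11 ranged from -0.094 to 0.057 and KRT19 from -0.016 to 0.25. The causes of these shifts were not tested. The pseudocount alternative did not apply to log2 values, and the seed-site test and its alternatives were not run.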

Other observations

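The lists and tests in this part were chosen after the results were seen, except that the predictions for cyclic loess were written before its result. The signs of RNA quality that differed between the groups also moved with each gene group in this part, and cannot be told apart from the treatment. Genes of fatty acid synthesis and of the LXR nuclear receptor pathway were lower in miR-20a cells in 14 of 20 measured members. SCD was the only member that fell past the threshold. FASN, the fatty acid synthase, had a change of -0.71 (limma adjusted p = 0.061), SREBF1, the transcription factor of lipogenesis, -0.65 (adjusted p = 0.063, limma), PLTP, the phospholipid transfer protein, -0.67, FADS2, a fatty acid desaturase, -0.63 and the cholesterol exporter gene ABCA1 -0.55. Their other probe sets were lower too but by less, the weakest at -0.29 for FASN, -0.07 for SREBF1, -0.16 for FADS2 and -0.06 for ABCA1. In the other direction, MYLIP rose and GPAM, the first enzyme of triglyceride synthesis, had a change of 0.69 (adjusted p = 0.082, limma). The list was lower by camera (p = 0.0051, p = 0.19 with an estimated correlation), but without the 6 genes that prompted it the p was 0.88, in the direction up with a median of -0.11.

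Genes of the BMP and SMAD feedback response were split, with 10 of 19 measured members higher and 9 lower and a median of 0.03 (camera p = 0.0015, p = 0.075 with an estimated correlation). Past the threshold 7 rose and 0 fell: ID1 (0.78), ID2 (1.16), ID3 (1.12), BAMBI (1.17), SMAD6 (0.64), SMAD7 (0.93) and GREM1 (0.89), while ATOH8 had a change of 0.60 (limma adjusted p = 0.053). After cyclic loess these 7 still had a median of 0.955 (0.636 to 1.18). They were picked for large changes, and the SDs of the arrays differed little (1.847 to 1.906). This normalization could therefore hardly have removed their rise, and unequal array spread stays undecided for them. A wider BMP and SMAD response may be a hypothesis, but for the list without the 5 genes that prompted it camera gave a p of 0.794, with a median of -0.09 while the test pointed up, so it stays undecided.

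Of 14 measured genes of the aryl hydrocarbon receptor, a ligand-activated transcription factor, 10 were higher and 4 lower, with a median of 0.10 (camera p = 0.00018, p = 0.11 with an estimated correlation). TIPARP (1.12), ALDH1A3 (1.07), CYP1B1 (0.97) and AHRR (0.92) rose, while NQO1 (0.39) and NFE2L2 (0.56) had adjusted p-values of 0.088 (limma) and CYP1A1, the classic target, had a change of 0.16 (limma adjusted p = 0.32). The other probe set of ALDH1A3 changed by only 0.04, and 2 of 3 probe sets of NFE2L2 were higher. The 4 lower members had changes between -0.16 and -0.03. After cyclic loess the 4 genes that rose still had a median of 0.899 (0.826 to 0.998). They too were picked for large changes, so unequal array spread stays undecided for them. A wider receptor response may be followed up, although for the list without the 4 prompting genes camera gave a p of 0.27, which leaves it open.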
